A study of Macaca mulatta with 2 samples.

How the data were processed

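Whole-genome bisulfite sequencing was done on prefrontal cortex of 2 male rhesus macaques (Macaca mulatta), one aged 21 years (replicate 1) and the other 13 years (replicate 2). Bisulfite converts unmethylated cytosine, which is then read as thymine, while methylated cytosine stays cytosine. The treatment does not separate methylated from hydroxymethylated cytosine, so each level covers both. Per the labels' protocols, paired-end libraries were made with methylated adapters, treated with bisulfite and amplified by PCR.

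Per the submitters' processing notes, Trim Galore, Bismark and BSMAP were used, without versions. The genome build, any removal of duplicate reads and any filters are not given in the sources used here. The authors deposited, for each animal, 1 table from Bismark and 1 from BSMAP, both aligners of bisulfite reads. The deposited unit is other than a single count, since each CpG carries 2 whole-number counts, the methylated calls and all calls. Both strands of a CpG were merged, and no normalization was applied to the deposited counts. The start positions of the deposited Bismark counts were counted from 1 and those of BSMAP from 0. After adding 1 to the BSMAP starts, 99.0% and 99.4% of the Bismark CpGs on placed chromosomes had a BSMAP partner in replicates 1 and 2.

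The methylation level of a set of CpGs was the sum of methylated calls divided by the sum of all calls, in percent. Bismark counts were the main source. A CpG entered a level with at least 5 calls unless stated otherwise. Autosomes 1 to 20 gave the genome-wide value, and X and the mitochondrial genome were kept apart. Both animals form 1 group, so values are given per animal and as mean and SD, and no test across animals or between ages was possible. Intervals for single shares are 95% Wilson or exact Clopper-Pearson intervals. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

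Local CpG density was the number of CpG positions in the 500 bp centred on a CpG, taken from all positions listed in any table. Low methylated stretches were runs of at least 4 CpGs, each with at least 5 calls and at most 2000 bp apart, whose running level over 3 CpGs lay under 50%. A run of at least 30 CpGs with a level under 10% was called an unmethylated region (UMR). A run of fewer than 30 CpGs at 10 to 50% was called a low methylated region (LMR). Overlap between animals was set against 100 shuffles of the regions along their own chromosome, without matching CpG density or coverage. Levels were also taken in bins of 100000 bp. Levels in bins, in stretches shared by UMRs of both animals and their flanks, and of regions in the other animal used CpGs with at least 1 call. So did the levels of the mitochondrial genome and of unplaced scaffolds. Windows of 1000 bp with at least 20 CpGs and 100 calls per animal took CpGs with at least 1 call in both animals.

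For the comparison of the animals, calls were summed in windows of 1000 bp over autosomal CpGs with at least 1 call in both. Windows with at least 5 CpGs and 50 calls per animal were tested with a two-sided Fisher's exact test, followed by Benjamini-Hochberg adjustment over all windows. A window was called different at an adjusted p under 0.05 and a difference of at least 20 points. The same test between alternate CpGs of 1 animal gave a rate within an animal. It was set beside rates between the animals over all calls, over different alternate CpGs and over the same alternate CpGs. The windows named with their positions are the 10 largest differences in each direction that passed with both aligners. For the aligners, they are the 5 largest in each direction shared by both animals. This rule, the tests of the comparisons and 56 sets of alternatives were chosen before the data were examined. Another 4 alternatives were added later, as were some tests of explanations, which the closing part names. The correlation across chromosomes was tested with 100000 two-sided permutations.

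The window test, the region calls and the correlation expected from sampling alone were tested on simulated data. At the real depths, 16.5% of windows changed by 20 points were called, 53.5% of those changed by 30 points and 87.5% of those changed by 40 points. Among the unchanged windows of the 1550932 simulated, 16 were called. The simulated calls were drawn as independent, while the real calls had a dispersion of 2.90 within an animal and 2.38 between the animals. These rates therefore do not give the false calls among the real windows. With the coverage of chromosome 20 in replicate 1, each of the 91 planted UMRs and 98 planted LMRs was found, with 0 calls elsewhere. These regions were planted in an even, highly methylated background with independent calls. The planted LMRs also held more CpGs than the median of 5 and 6 in the LMRs called in replicates 1 and 2. The recovery of shorter regions, and false calls in an uneven background, were therefore not tested. The correlation was simulated on chromosome 20 alone. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

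The alternatives were minimums of 3 calls, 10 calls and none, the BSMAP counts, unweighted means and a maximum of coverage at its 99.9th percentile. Others changed window sizes and window minimums, thresholds of 10 and 30 points, smoothing over 5 CpGs, reciprocal overlap and calls scaled down by their dispersion. Each animal was also left out in turn. A genome sequence and an annotation in the coordinates of these counts were not used here. The gene table at hand is on assembly T2T-MMU8v2.0 and differs in chromosome lengths, as its last gene on chromosome 12 ends 40961409 bp past the last CpG of the counts. Gene features, promoters, gene bodies, CpG islands and 20 gene lists fixed beforehand were therefore not analysed here. No Y chromosome was listed. Unplaced scaffolds were left out of the comparisons.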

Results

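The methylation of CpG sites was measured by whole-genome bisulfite sequencing in prefrontal cortex of 2 male rhesus macaques, the macaque part of a comparison of brain methylomes between species. The animals were 21 years (replicate 1) and 13 years old (replicate 2), and each is 1 biological replicate of a single group. The Bismark counts held 208106008 calls in replicate 1 and 228784604 in replicate 2. On placed chromosomes they covered 23544572 and 24047332 CpGs with a median of 7 and 8 calls, and 72.1% and 77.5% of these CpGs had at least 5 calls. The BSMAP counts from the same animals held 144693258 and 201200720 calls, with a median of 5 and 7 per CpG. Confidence intervals here cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Positions are in the coordinates of the deposited counts, whose genome build is not given in the sources used here, and no gene names are attached to them.

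Most CpGs of the macaque prefrontal cortex were methylated. The autosomal level was 79.4% ± 0.166 (mean ± SD, n = 2), with 79.5% in replicate 1 (95% Wilson interval 79.47 to 79.48) and 79.2% in replicate 2 (79.24 to 79.25). CpGs at or above 80% made up 67.7% ± 0.682 of those with at least 5 calls. CpGs at or below 20% made up 8.25% ± 0.223, and the remaining 24.0% ± 0.905 lay between. Replicate 1 minus replicate 2 was 0.235 points over each animal's own CpGs and -0.0419 points over CpGs covered in both. With no minimum of calls the share at or below 20% was 11.5%, and with a minimum of 10 calls it was 5.88%, while the autosomal level stayed between 78.8% and 80.1% across the alternatives.

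**Figure D1:**
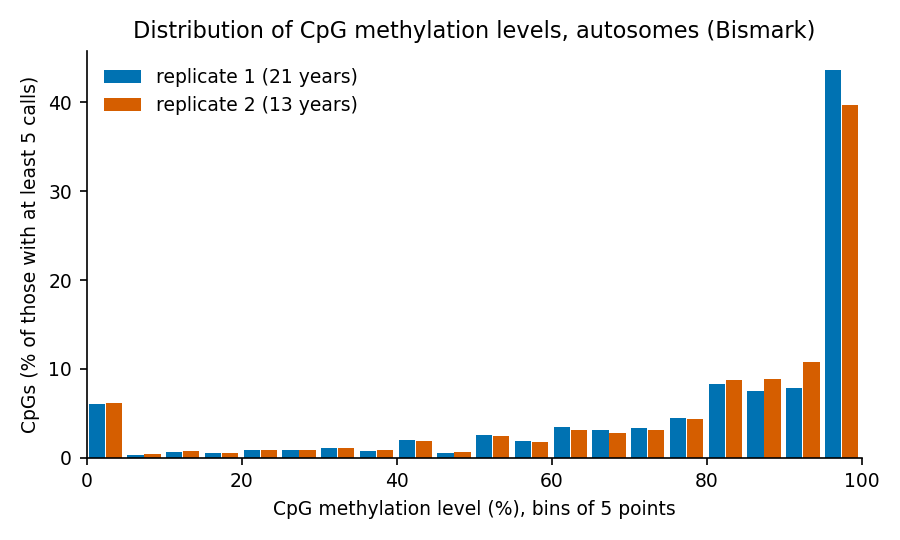
Share of autosomal CpGs (percent, y axis) by methylation level (percent, x axis) in each animal, for CpGs with at least 5 Bismark calls. Both animals had most CpGs at the high end, with 67.2% and 68.2% at or above 80%.

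The mitochondrial genome, which gives a measure of background calls because CpGs there are expected to be almost unmethylated, was listed in the Bismark counts alone. It had a level of 0.242% in replicate 1 (453 of 187290 calls, exact Clopper-Pearson 95% interval 0.220 to 0.265). The level in replicate 2 was 0.188% (355 of 188647 calls, interval 0.169 to 0.209). The mean was 0.215% ± 0.038 (SD, n = 2), and 0 mitochondrial CpGs reached 5%.

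Methylation depended on local CpG density. CpGs with 1 to 5 positions in the surrounding 500 bp had a level of 80.7% ± 0.0477 (mean ± SD, n = 2), and those with 6 to 10 had 81.5% ± 0.0137. The level was 79.97% ± 0.0478 at 11 to 15 positions and 71.1% ± 0.527 at 16 to 25. In the densest class, with over 25 positions, it was 20.9% ± 1.89, and 72.7% and 75.6% of the CpGs lay at or below 20%. The densest minus the sparsest class was -58.4 points in replicate 1 and -61.2 points in replicate 2, a difference far larger than the 2.67 points between the animals in the densest class. With density counted in 200 bp, and the class limits scaled to that length, the difference of the classes was -30.8 points.

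Dense CpGs were covered less well than sparse ones. At least 5 calls were present at 29.6% and 39.8% of the densest positions, against 85.9% and 90.3% of the sparsest. Over CpGs covered in both animals, the densest class had 19.7% in replicate 1 and 19.2% in replicate 2, compared with 22.3% and 19.6% over each animal's own CpGs.

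**Figure D2:**
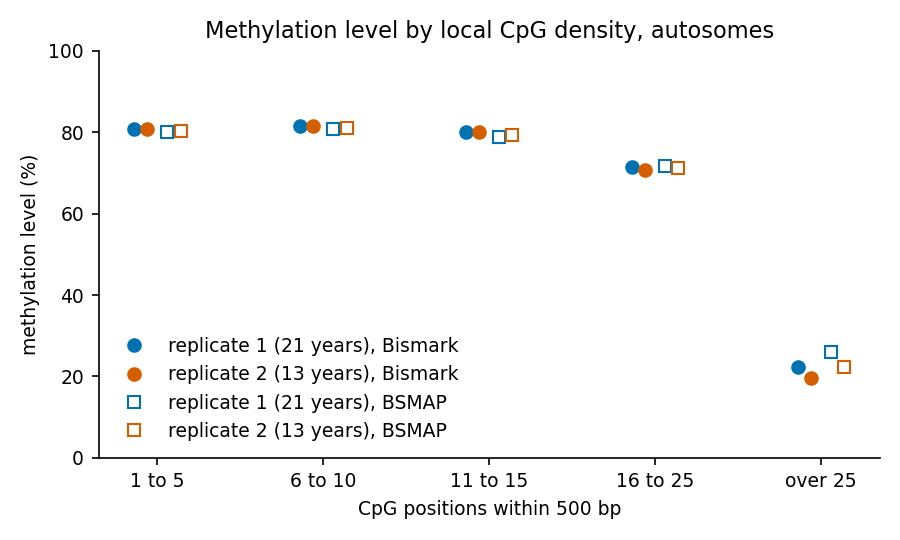
Methylation level (percent) by the number of CpG positions in the surrounding 500 bp, with filled points for the Bismark counts and open squares for the BSMAP counts of both animals. The Bismark level was near 80% up to 15 positions and 20.9% above 25.

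Chromosomes differed most at chromosome 19. Its level was 72.7% ± 0.640 (mean ± SD, n = 2), and its difference to all autosomes was -6.28 points in replicate 1 and -6.95 points in replicate 2. Chromosome 16 was next with 77.3% ± 0.112, and the highest autosomes were 12 with 80.6%, 18 with 80.5% and 17 with 80.4%. Chromosome 19 had 13.5 CpG positions per kb, the highest of the autosomes. Of its CpGs with at least 5 calls, 7.76% (mean of both animals) were in the densest class. It was also lowest among CpGs of the sparsest class, with 76.2%.

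Across the 20 autosomes, chromosomes richer in CpGs were less methylated. Pearson's r between CpG positions per kb and the mean level was -0.811 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Spearman's rho was -0.717 (permutation p = 6e-04). Without chromosomes 16 and 19, the farthest from the median density, r was -0.618 (permutation p = 0.004) and rho was -0.612. This was the 1 relation tested across chromosomes, and chromosomes are not replicates. Chromosomes 19 and 16, the richest in CpGs, also had the fewest calls per CpG of the autosomes. The mean was 5.87 and 6.22 calls on chromosome 19 and 6.97 and 7.41 on chromosome 16, in replicates 1 and 2. On all autosomes it was 8.73 and 9.40. CpG content and depth were not separated across chromosomes, so the correlation may include an effect of depth.

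The X chromosome, present in 1 copy in males, had a level near that of the autosomes in the Bismark counts. It was 80.5% in both animals, above the autosomes by 1.07 and 1.28 points (1.18 ± 0.149, mean ± SD, n = 2). The direction did not hold throughout. With a minimum of 10 calls the difference was -0.284 points (-0.327 and -0.242), and with the BSMAP counts it was -0.301 points (-0.799 and 0.196). With both changes together the BSMAP level of X was 70.7% and 75.8%, against 78.97% and 79.6% on autosomes. X CpGs had a mean of 5.48 and 5.79 calls, against 8.73 and 9.40 on autosomes.

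**Figure D3:**
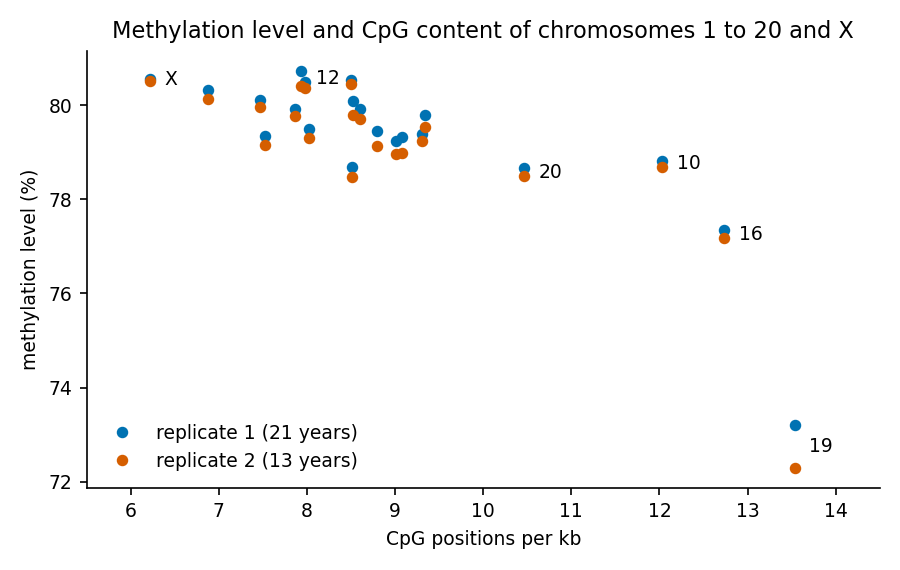
Methylation level (percent, y axis) of each autosome and X against CpG positions per kb (x axis), with the values of both animals. Chromosome 19, at 13.5 positions per kb and 72.7%, lies lowest.

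Unmethylated regions, the stretches where regulatory DNA such as CpG island promoters usually lies, were called in each animal by itself. Replicate 1 had 5910 UMRs over 15.5 Mb and replicate 2 had 8015 over 19.1 Mb (6962.5 ± 1488, mean ± SD, n = 2). The median UMR length was 2163 bp and 1994 bp. LMRs, the shorter stretches at intermediate levels, numbered 63728 and 74709 (69218.5 ± 7765), with median lengths of 431 bp and 405 bp. UMRs of replicate 1 overlapped a UMR of replicate 2 in 84.4% of cases, and 62.4% of those of replicate 2 overlapped one of replicate 1. Shuffled regions overlapped in 1.63% on average and at most 1.96%. Of the LMRs, 55.5% and 47.7% overlapped one of the other animal, against 3.26% after shuffling. Shuffled regions could fall anywhere on the chromosome, while real ones need enough covered CpGs. An overlap above that of the shuffles therefore follows in part from where regions can be called. The number of UMRs changed with the setting, as a mean of 825 was called with a minimum of 10 calls, 10504 with a minimum of 3, and 4452.5 with the BSMAP counts (2437 in replicate 1 and 6468 in replicate 2).

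Regions called in 1 animal were low in the other as well. UMRs of replicate 1 had a median level of 4.94% in replicate 2, and those of replicate 2 had 5.12% in replicate 1. LMRs of replicate 1 had a median of 29.3% in their own animal and 37.2% in the other. For LMRs of replicate 2 these medians were 29.9% and 40%. Of the LMRs with enough calls in the other animal, 73.5% and 69.8% lay under 50% there, while 5.34% and 5.61% lay at or above 70%.

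Shared UMRs were taken as the stretches where UMRs of both animals overlapped. Outside them, methylation levelled off within 1000 bp. A run ends where the level over 3 CpGs reaches 50%, so the low level inside and the rise at the border follow largely from the definition. The mean level was 3.85% ± 0.0379 inside (mean ± SD, n = 2). It was 54.1% ± 0.437 within 250 bp outside and 71.0% ± 0.100 from 250 to 500 bp. From 500 to 1000 bp it reached 74.9% ± 0.293, and from 2000 to 5000 bp it was 73.3% ± 0.548.

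**Figure D4:**
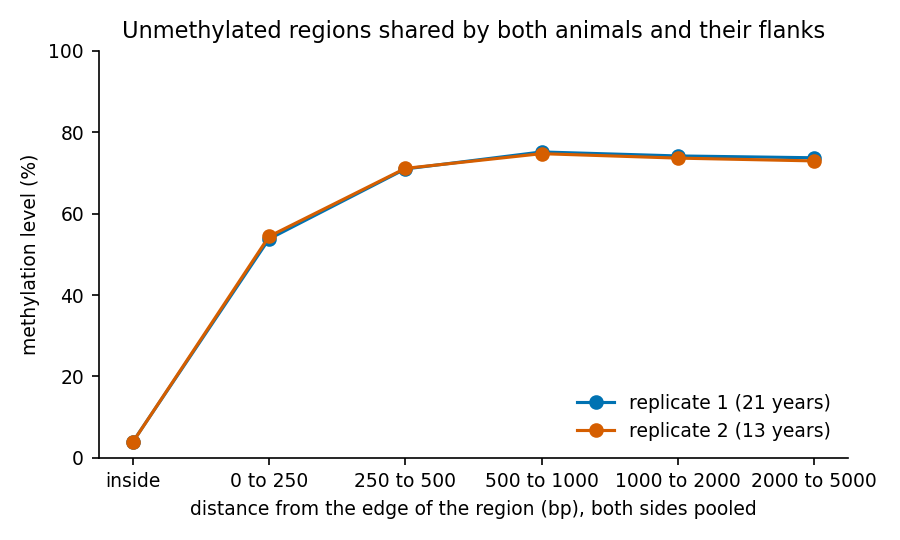
Methylation level (percent) inside shared UMRs and at increasing distance outside them (bp), for both animals. The mean rose from 3.85% inside to 71.0% at 250 to 500 bp.

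The stretches where UMRs of both animals overlapped numbered 5022 and covered 12.4 Mb, with 257 of at least 5000 bp and 53 of at least 10000 bp. A UMR that overlapped several of the other animal gave several stretches. The longest ones, singled out after their values were seen, are long unmethylated valleys. The longest spanned 32613 bp on chromosome 6, from 85346375 to 85378987, at 4.52% and 5.81%. The next spanned 31879 bp on chromosome 2, from 106452570 to 106484448, at 7.15% and 6.22%. On chromosome 6 another ran from 49332312 to 49356773 at 8.32% and 8.02%. X carried 46 and 92 UMRs, or 0.296 and 0.592 per Mb, against 2.16 and 2.94 per Mb on autosomes. Fewer positions could enter a UMR on X, where 11.8% and 15.2% of the densest ones had at least 5 calls, against 29.6% and 39.8% on autosomes. Among windows with at least 20 CpGs and 100 calls per animal, 37.3% on X and 16.7% on autosomes lay under 35% in both animals.

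Low methylation at a larger scale was confined to few places. The median of 26031 bins of 100 kb was 80.2%, with 5th and 95th percentiles of 69.2% and 85.8%. Only 117 bins lay under 50%. Of the 1504 bins under 70%, 172 were on chromosome 19, which has 525 bins. The 4 lowest bins, also chosen after their values were seen, stood apart from the next at 27.0%. They were 39400001 to 39500000 on chromosome 12 (11.4% and 10.9%) and 34700001 to 34800000 on chromosome 16 (13.0% and 13.5%). The others were 99600001 to 99700000 on chromosome 3 (15.4% and 15.3%) and 51200001 to 51300000 on chromosome 11 (15.8% and 17.2%). Pearson's r between the animals was 0.966 across bins, which are not independent replicates.

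The methylomes of both animals were alike across sites. Across 14643881 CpGs with at least 5 calls in both, Pearson's r was 0.723 and Spearman's rho 0.549. Identical levels with independent calls would have given an r of 0.874 at this depth, and calls that are not independent would lower that value. Across 1550932 windows of 1 kb, r was 0.867 and rho 0.736, where identical levels with independent calls would have given 0.949. CpGs and windows are not independent replicates.

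In 79.1% of the windows the animals differed by under 10 points. Fisher's exact test, with the threshold of 20 points, called 36632 windows different (2.36%), of which 18481 were higher in replicate 1 and 18151 in replicate 2. Called windows had a median absolute difference of 24.4 points. By the mean level of both animals, windows at 20 to 50% were called in 6.15% of cases and those at 50 to 80% in 5.12%. The rate was 0.314% under 20% and 0.900% at or above 80%. Windows with a mean near either end of the scale cannot differ by 20 points, so the lower rates there follow in part from the threshold. Of the called windows, 26297 were also tested with the BSMAP counts, 26251 of these differed in the same direction, and 9031 were called with both aligners. Both aligners used the same reads, so a shared direction is not independent evidence for a difference.

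The count depends strongly on how far calls are scaled down for their dispersion. Alternate CpGs within 1 animal, compared in the same way, were called in 7.75% and 7.29% of windows. In the same windows, 1.79% and 1.94% were called between the animals over all calls, and 9.83% and 9.94% when each animal gave a different set of alternate CpGs. Both animals had 50 calls on the same alternate CpGs in 467283 and 483561 of these windows, of which 2.06% were called over those CpGs. In the same subsets, 7.23% and 6.56% were called within an animal and 9.42% and 9.49% over different alternate CpGs, so these rates include differences between the CpGs of a window. The dispersion of calls was 2.90 within an animal and 2.38 between the animals. The former includes differences between the CpGs of a window, and the latter the differences between the animals that were tested. Over the same alternate CpGs in both animals it was 2.18 in both subsets. Neither scaling below is thus a correction for non-independent calls alone. With calls scaled down by the dispersion within an animal, 59 windows were called, and 284 with the dispersion between the animals. Since each age is represented by 1 animal, the windows describe these animals and not age.

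The largest differences called with both aligners ranged from 54.6 to 71.7 points higher in replicate 1, and from 57.7 to 73.0 points higher in replicate 2. On chromosome 15, the window from 67920001 to 67921000 had 93.6% in replicate 1 (95% Wilson interval 86.6 to 97.0) and 21.8% in replicate 2 (13.0 to 34.4), over 6 CpGs (adjusted p = 3.8e-15, Fisher's exact test). Also on chromosome 15, the window from 65776001 to 65777000 had 13.2% (7.12 to 23.3) and 86.2% (77.0 to 92.2) over 5 CpGs (adjusted p = 1.8e-15, Fisher's exact test). The windows with most CpGs lay on chromosomes 19, 13 and 4. On chromosome 19, from 63875001 to 63876000, 111 CpGs had 5.87% (4.01 to 8.52) and 66.2% (60.9 to 71.0; adjusted p = 3.2e-69, Fisher's exact test). On chromosome 13, from 74616001 to 74617000, 59 CpGs had 16.4% (11.8 to 22.3) and 80.2% (74.0 to 85.2; adjusted p = 1.5e-32, Fisher's exact test). On chromosome 4, from 166091001 to 166092000, 38 CpGs had 95.5% (91.3 to 97.7) and 36.9% (30.7 to 43.5; adjusted p = 2.1e-32, Fisher's exact test). These p-values take calls as independent. With calls scaled by the dispersion within an animal, the adjusted p of Fisher's exact test was 0.0073 and 0.0092 for the windows on chromosome 15. It was then 5.3e-21 on chromosome 19, 3.4e-08 on chromosome 13 and 6.4e-08 on chromosome 4 (Fisher's exact test). A window on chromosome 7 from 14022001 to 14023000, with 73.8% and 14.4%, fell to a difference of 13.1 points and was no longer called without its CpGs of extreme coverage.

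The other windows higher in replicate 1 start at 32116001 on chromosome 2, 79845001 on chromosome 11, 76996001 on chromosome 17 and 55329001 on chromosome 9. On chromosome 3 they start at 22603001, 80967001 and 8798001. Those higher in replicate 2 start at 84162001 on chromosome 15, 39146001 on chromosome 18, 33021001 on chromosome 2 and 54795001 on chromosome 3. On chromosome 5 they start at 153846001, 111860001 and 80939001. Of all 20 named windows, 8 were no longer called with the dispersion within an animal and 4 with that between the animals. With a minimum of 5 calls per CpG, 14 could be tested, and 0 of these were no longer called. Those starting at 67920001 and 65776001 on chromosome 15, at 55329001 on chromosome 9 and at 153846001 on chromosome 5 could not be tested. The same held for the windows on chromosomes 19 and 13. Their 111 and 59 CpGs held 426 and 189 calls in replicate 1, and 331 and 192 in replicate 2.

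**Figure D5:**
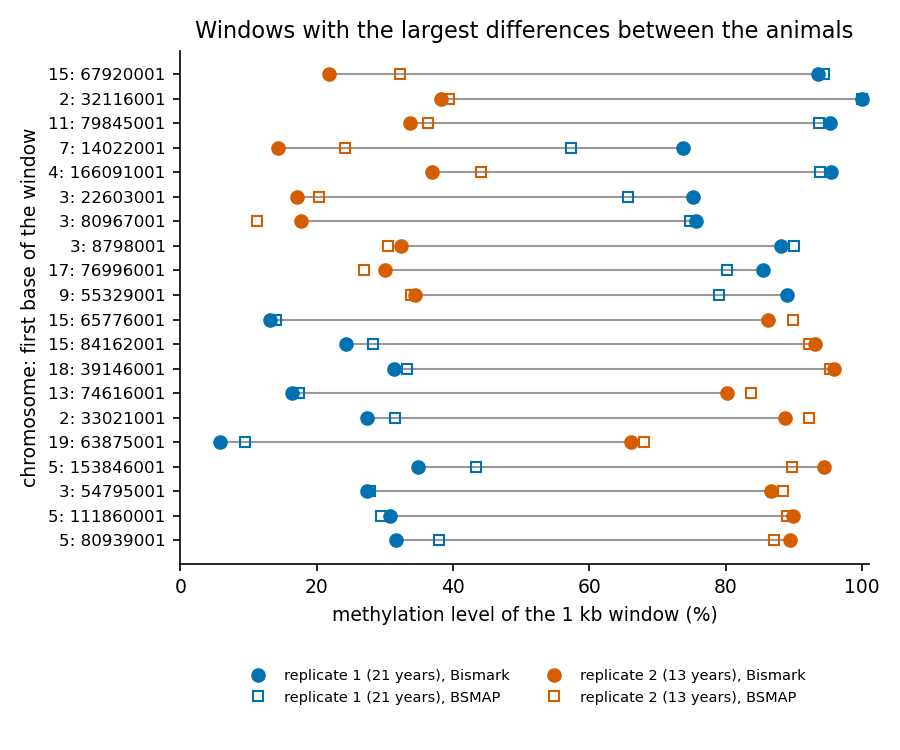
Methylation levels (percent) of the 20 named windows of 1 kb in replicate 1 and replicate 2, with the chromosome and first base on the y axis, filled points for the Bismark counts and open squares for the BSMAP counts. The Bismark differences range from 54.6 to 73.0 points in size.

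The aligners gave nearly the same levels from the same reads. At 13198772 and 16939331 CpGs with at least 5 calls from both, BSMAP minus Bismark was -0.588 and -0.379 points. Pearson's r between the aligners was 0.966 and 0.978 across CpGs, which are not replicates. The share of CpGs that differed by at least 20 points was 2.70% and 1.78%. The median ratio of BSMAP to Bismark calls per CpG was 0.692 and 0.875.

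Large disagreement shared by both animals was rare in windows and went mostly one way. Single CpGs were split more evenly. BSMAP was lower by at least 20 points at 1.64% and 1.12% of CpGs, and higher at 1.07% and 0.659%. Of 846008 windows of 1 kb compared, 495 (0.0585%) differed by at least 20 points in the same direction in both animals. BSMAP was lower in 488 of these and higher in 7. With a minimum of 10 calls, 154 of 128139 windows compared did so. The largest difference lay at the start of chromosome 6, from 1 to 1000, with 95.8% and 96.9% in the Bismark counts and 10.96% and 13.3% in the BSMAP counts. Next were the windows starting at 71039001 on chromosome 5, 16194001 on chromosome 3, 20915001 on chromosome 6 and 113048001 on chromosome 2. Those with higher BSMAP levels start at 9727001 and 88582001 on chromosome 13, 93663001 on chromosome 2, 39533001 on chromosome 8 and 63939001 on chromosome 1. At the first of these, Bismark gave 46.4% and 19.9%, and BSMAP gave 77.2% and 65.3%.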

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

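Unplaced scaffolds, which none of the comparisons use, held a clear signal, and that signal is the reason they are listed here. Their methylation level was 69.1% in replicate 1 and 67.3% in replicate 2 in the Bismark counts. In the BSMAP counts it was 60.0% in replicate 1 and 59.0% in replicate 2. These levels used all CpGs with at least 1 call. At that minimum the autosomal level was 78.9% and 78.7% in the Bismark counts, and 78.2% in both animals in the BSMAP counts. All 4 scaffold values lie below the autosomal level of the same animal and aligner. The scaffolds held 2.53% and 2.60% of the Bismark calls, and 2.05% and 2.09% of the BSMAP calls. Bismark listed 19919 and 20300 scaffolds and BSMAP listed 994 and 993, so the aligners' values rest on different sets of sequences. No technical or biological explanation was tested for the lower level.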

How the results depend on the processing

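The scaling by the dispersion between the animals, the minimum of 5 calls per CpG in windows, the thinning of both aligners and the densest class over shared CpGs were chosen after the data had been seen. Leaving out single animals aside, 37 of 90 alternatives over 18 results counted as unchanged. Levels and shares did so if they moved by less than the spread of the animals, and counts if they stayed within 1.5 times. The correlation across chromosomes did so if it kept its sign and a permutation p under 0.05. For Pearson's r between the animals, any change counted as moved. The difference of X and autosomes reversed to -0.284 points with a minimum of 10 calls and to -0.301 with BSMAP, and was 2.06 unweighted. The autosomal level was 80.1%, 79.0% and 78.8% with minimums of 10, 3 and none. It was 79.1% with BSMAP, 78.8% unweighted and 79.8% over CpGs covered in both animals. The share at or above 80% was 69.0%, 66.0% and 65.8% with these minimums and 68.5% with BSMAP. The share at or below 20% was 5.88%, 9.51%, 11.5% and, with BSMAP, 7.48%. The share between was 25.1% with a minimum of 10 and 22.7% with none. The densest minus the sparsest class was -56.1 points with BSMAP, -30.8 in 200 bp and -67.7 in 1000 bp. Chromosome 19 minus autosomes was -5.93 points with a minimum of 10 and -7.15 with none. Pearson's r across chromosomes was negative in all 7 alternatives, from -0.829 to -0.791, with permutation p of 3e-05 or less.

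UMRs numbered 825, 10504 and 4452.5 with minimums of 10 and 3 and with BSMAP (2437 in replicate 1 and 6468 in replicate 2), and 50.3% overlapped with a minimum of 10. LMRs numbered 34171 with a minimum of 10, where 46.0% overlapped. With the minimum of 5, 30.8% of LMRs overlapped reciprocally. Fewer CpGs pass a higher minimum, which shortens the list of possible regions by construction. The windows called different were 74456 and 6105 at 10 and 30 points, 11631 with BSMAP, 7615 with at least 10 CpGs and 100 calls, and 14482 of 2 kb. Scaling calls by the dispersion gave 59 (within an animal) and 284 (between). Thinned to the lower of both aligners per CpG, Bismark gave 17490 and BSMAP 10960. The aligners differed the same way in 154 windows with a minimum of 10, in 3747 at 10 points and in 110 at 30 points. Within single animals, over larger sets of windows and without sharing, they numbered 1352 to 1492, and 1358 and 960 over the windows compared in both. CpGs that differed between the aligners made up 0.928% and 3.498% with minimums of 10 and 3, and 10.7% and 0.564% at 10 and 30 points. Pearson's r between the animals was 0.723 and 0.726 across CpGs with minimums of 10 and 3, and 0.727 with BSMAP. Across windows it was 0.892 with BSMAP, 0.906 in 500 bp and 0.866 in 2 kb. Apart from changes that follow from fewer sites, other thresholds or fewer effective calls, the cause was not tested. A median of 7 and 8 calls per CpG limits single CpGs. Alternatives for gene features, promoters, gene bodies and islands were not run.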

Other observations

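The bounds for the rate within an animal, the rate over the same alternate CpGs, the share by BSMAP depth, the interval of the X share of dense windows, that share without low windows and the HOX test were chosen after the results had been seen. Among CpGs with at least 10 calls in both animals, 31147 of 6167352 (0.505%) differed by 80 points or more, 15059 higher in replicate 1 and 16088 higher in replicate 2. The lower animal was at exactly 0 in 75.6% of them. A C to T variant that removes the CpG in 1 animal may be a cause, since such a site reads as unmethylated while its neighbours keep their methylation. Of the 25573 such CpGs with neighbours within 200 bp, 10.9% had neighbours that differed by 20 points or more in the same direction as the CpG, and 1.88% by 50 points or more. At the remaining 89.1% the neighbours differed by less, not at all or the other way, and at 83.3% the difference was under 20 points in either direction. No genotypes were used, so this remains a hypothesis.

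CpG-dense windows at intermediate levels formed another class. Of 139985 autosomal windows with at least 20 CpGs and 100 calls per animal, 10603 (7.57%) lay at 35 to 65% in both animals. They formed 10000 runs, of which 551 spanned at least 2 adjacent windows and 47 at least 3. The runs with most windows, picked out after their values were seen, include 3994001 to 3998000 on chromosome 19 (51.4% and 49.6%) and 81118001 to 81122000 on chromosome 10 (50.6% and 52.1%). The other runs as long lay farther from 50%. They start at 1132001 on chromosome 14 (46.85% and 55.2%), 3041001 on chromosome 15 (52.3% and 56.3%) and 427001 on chromosome 9 (57.5% and 53.6%). Methylation of 1 of 2 parental copies could give such levels, and parts of X that males carry in 1 copy cannot show it. On X the share was lower, 5.76% of 938 windows (two-sided Fisher's exact test p = 0.035). X also held more windows under 35% in both animals, 37.3% against 16.7%. Among the other windows the share was 9.18% on X and 9.09% on autosomes, so the lower share on X goes with its larger number of low windows. That count leaves out windows by their own level, and whether parental copies act at some autosomal windows stays open. The share on X (95% Wilson interval 4.44 to 7.44) still lay above 50% of the autosomal one. Parental copies cannot act where males carry 1 copy of X, but any part carried in 2 copies was not left out. The share on X would argue against parental copies at most autosomal windows only if windows on X are in 1 copy and other causes act as on autosomes. The larger share of low windows on X leaves that condition in doubt, so no conclusion is drawn. Single windows at intermediate levels were not tested.

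The 4 lowest 100 kb bins lie on chromosomes 12, 16, 3 and 11. A candidate explanation is that they hold the 4 HOX clusters, which are long, rich in CpGs and commonly unmethylated in tissues. The gene table, although on another assembly, places HOXD, HOXB, HOXA and HOXC genes on these same chromosomes. For 4 bins drawn from the 500 richest in CpGs, the probability of falling 1 on each was 0.000125. The bins were seen before this test was chosen, so that probability is no chance value in support of the idea. The match is by chromosome, not by position, so the identity of the bins stays an open hypothesis.

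Windows called different between the animals were weighed against technical causes. Calls on the same read or copies of a read are not independent, and the rate within an animal was 76.1% of that between the animals over different alternate CpGs (78.9% and 73.3%, and 47.3% and 96.3% with BSMAP). Both rates include differences between the CpGs of a window, since 7.75% and 7.29% were called within an animal, but 1.79% and 1.94% between the animals over all calls, so non-independent calls stay open. Single variant CpGs stay open as a cause. Without their most different CpG, 42.6% of called windows kept 20 points, against 81.3% in simulated windows with even differences and independent calls. Simulated windows counted only if they reached 20 points. Their median without that CpG was 24.6 points, against 24.4 points in called windows before its removal. They are no matched baseline, so the gap cannot separate single variants from other differences between the CpGs of a window. Called windows lay outside the central 98% of the depth ratio between the animals 1.23 times as often as all windows (2.45% against 1.995%). Extreme differences in depth between the animals are therefore an unlikely cause of most called windows. The ratio cannot show windows that are deep in both animals, or smaller differences in depth, so these stay open. Without CpGs of extreme coverage, 36523 windows were called, against 36632 with them. Age, cell composition and genotype stay open as untested, with 1 animal for each age. The 647 adjacent pairs of called windows with the same direction exceeded the 290 of shuffled windows (at most 325). Pairs with opposite directions numbered 294, against 291 in shuffled windows (at most 338). Reads that cross a border put non-independent calls in both windows, and shuffling removes that link. The excess therefore cannot separate the causes named here.

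The windows where BSMAP and Bismark differ the same way in both animals have no biological explanation that was tested, as the reads are the same. Reads placed by only 1 aligner may be a cause, because the median BSMAP to Bismark depth ratio was 1.81 times that of all windows (1.85 and 1.78). In the 488 windows with lower BSMAP levels, BSMAP was deeper than Bismark in 81.3% and 99.4%, compared with 0.986% and 5.28% of all windows. Collapsed repeats, where reads of several copies stack up, may contribute in the BSMAP counts, since 60.2% of the 495 windows exceeded the 99th percentile of BSMAP depth, against 1.45% of all. By Bismark depth, the measure chosen beforehand, this share was 6.67%, against 1.62% of all, and by its bound this argued against collapsed repeats. BSMAP depth is also part of the depth ratio above, so its share is not separate evidence.

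The sign of X minus autosomes, which changed with the minimum of calls, was weighed against depth and density. With autosomal calls thinned at random to the depth of X, the difference at a minimum of 10 calls was -0.214 points (-0.234 and -0.195). Lower depth alone, with calls lost at random, is therefore unlikely to explain the sign. Random thinning cannot mimic a minimum of calls that selects X CpGs of unusual depth, so such a selection stays open. With X standardised to the autosomal density classes, the difference at a minimum of 10 calls was -0.653 points (-0.605 and -0.702). This argues against CpG density as the source of the negative sign. X was not standardised at a minimum of 5 calls, so the part of density in the positive difference was not tested. At a minimum of 5 calls the thinned difference was 0.742 and 0.875 points. No biological explanation was tested, and what sets the sign stays open.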
